A study of Mus musculus with 6 samples.

How the data were processed

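RNA was measured in epithelial cells taken from the gastric corpus of mice, in 3 libraries of normal stomach from wild-type mice and 3 libraries of Yap-activated gastric cancer. Per the labels, the mice with Yap activation carried 3 alleles: CreERT2 at the Clu gene, rtTA at the Rosa26 locus and an HA-tagged Yap transgene. CreERT2 is a Cre recombinase that tamoxifen switches on, and rtTA is a transcriptional activator that needs doxycycline. Per the labels' protocols, mice of both groups received 2 mg tamoxifen on each of 5 days and then doxycycline in food for the last 14 days. The corpus epithelium was released with EDTA and was not cultured. Libraries were made with a stranded poly(A) kit (TruSeq Stranded mRNA) and sequenced as paired 50 bp reads.

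The authors deposited 1 table of whole-number read counts per gene symbol for the 6 libraries, with no normalization. The submitters' processing notes name STAR 2.4.2a, DESeq2 and the builds GRCm38 and mm10. The counting program, its strand setting, the gene annotation and the handling of reads that match several places are not given in the sources used here. Reads of an overlapping gene on the opposite strand, of a close paralog or of a pseudogene can therefore sit in a gene's count. Among genes named here this applies to ribosomal protein genes, Hspa1a and Hspa1b, Hbb-bs and Hbb-bt, Cyp21a1, and genes overlapped on the opposite strand such as Tmprss9, Glipr1, Tead2, Dusp1, Cxcl16 and Plvap. Coordinates were taken from GENCODE mouse release 21 on GRCm38, in which 21523 of the 21526 symbols in the table were found. All columns of the table were used.

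Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given and its minimum count of 10, which left 14600 genes. Libraries were scaled by TMM, and each gene was tested with edgeR's robust quasi-likelihood F-test of Yap-activated against Normal over all 6 libraries, with no other term in the model. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Expression is given as TMM-scaled CPM (counts scaled to a common library total), and the SE of a log2 fold change is the fold change divided by the square root of F. Library totals ran from 25580734 to 48440033 counts. P-values measure the spread between these libraries, which may be technical in part, since the labels do not say that each came from a separate mouse. Intervals on read ratios are exact 95% binomial intervals and cover counting error only.

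The genes named and the gene lists were fixed before the data were examined, as were the tests and the alternatives, except where the text says that they were chosen afterwards. The named genes are a fixed set of gastric and Yap-related genes, the 10 largest rises and the 10 largest falls, and members of each list. The rises and falls had to pass the threshold, reach a mean of 10 CPM in the higher group, show no overlap between the groups and have a symbol that is not a provisional one. In each list the 3 members with the smallest p and the member with the highest mean CPM were taken. Other list members are printed as examples that were picked after their values were seen. In total 37 lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. Adjusted p-values of these lists are Benjamini-Hochberg values over the 37 lists. For lists added after the data were seen they are values over the 37 lists and the added lists together, and for gene families taken from symbols over the 244 families.

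The gene test was tested on simulated data, in 5 sets of counts for the 14600 genes of Yap-activated against Normal. It recovered 12.4% of genes changed 1.5-fold, 56.0% of those changed 2-fold, 85.2% at 4-fold and 96.0% at 8-fold. Of its 687 calls, 9.17% were false, which is above the threshold used. Each fold was given to 250 genes over the 5 sets, a far smaller share of genes than the 59.5% called in the data. The shares recovered and the share of false calls may therefore not hold for the real comparison. In a simulation of the lists, camera called both of the 2 changed lists and none of the others. Simulated genes vary independently, so this simulation does not test the preset correlation.

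The alternatives were other scalings (DESeq2 size factors, library totals alone, upper quartile, TMM without the 50 most abundant genes), no filter, a filter of 1 CPM in 3 libraries, non-robust dispersions, DESeq2 1.42.0, limma voom, a replicate block, leaving out each library, thinning all libraries to the smallest total, and a test against a 2-fold change. For the lists they were an estimated correlation, fry, ranks, and members found in no other list. Non-robust dispersions do not enter the list test.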

Results

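The data are read counts for 21526 gene symbols in 6 libraries of gastric corpus epithelium, 3 from normal stomach (Normal) and 3 from Yap-activated gastric cancer. Totals ran from 36815754 to 48440033 counts in Normal and from 25580734 to 44295619 in Yap-activated libraries. The comparison asks which genes differ between the normal corpus and corpus tissue in which Yap, the transcriptional coactivator restrained by the Hippo pathway, has been activated. Normal mice were wild-type, so effects of the CreERT2 and rtTA alleles cannot be told apart from those of Yap.

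In Yap-activated tissue all 18 genes of acid-secreting parietal cells, all 8 tested genes of pepsinogen-secreting chief cells and 70 of 75 nuclear-encoded genes of oxidative phosphorylation fell, while 18 of 22 Yap and Taz target genes, 17 of 18 genes of fetal-like epithelium and 18 of 19 cytokine and chemokine genes rose. These lists passed camera's test with the preset correlation (adjusted p from 2.39e-19 to 5.66e-05), but not with an estimated correlation (adjusted p from 0.17 to 0.245 with an estimated correlation). They also passed fry, which tests each list by itself (adjusted p from 5.66e-05 to 0.001). Fry does not ask whether a list changed more than other genes, and 59.5% of all genes tested were called. With the preset correlation, splits of the libraries that mix the groups also called 16 to 23 lists. Such splits keep part of the difference between the groups, so this is not a rate of false calls. RNA was measured over all cells together, so a change in the mix of cells cannot be told apart from a change within cells. Atp4a, the catalytic subunit of the gastric proton pump, went from 18324 ± 3050 to 22.8 ± 3.80 CPM, and Pgc, the pepsinogen C gene, from 111582 ± 24929 to 168 ± 16.9 CPM (SD, n = 3). Yap1 rose from 104 ± 2.94 to 2068 ± 885 CPM, and Ankrd1, a Yap target, from 0.224 ± 0.0773 to 93.2 ± 60.2 CPM (SD, n = 3).

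Of 14600 genes tested, 4345 were higher and 4337 lower in Yap-activated tissue, 59.5% in all. By over 2-fold, 2465 were higher and 2348 lower. By over 4-fold the numbers were 1192 and 994, and by over 16-fold 322 and 268. The groups did not overlap at 67.6% of genes, where chance gives 10%. With library totals alone in place of TMM, the median of all genes moved up by 0.49 log2, and 76.6% of calls were higher against 50.0% with TMM. Against a 2-fold change as the null, 1594 genes were higher and 1454 lower. The 10 most abundant genes held 33.5 ± 4.33% of counts in Normal and 12.1 ± 2.90% in Yap-activated libraries (SD, n = 3; 2-sided exact permutation p = 0.1, the smallest that 3 against 3 can give).

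Yap1 lies on the minus strand of chromosome 9 from 7931999 to 8004596 (GRCm38). Its log2 fold change was 4.32 (SE 0.31, adjusted p = 2.19e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and it was higher in 3 of 3 Yap-activated libraries. Yap-activated replicate 1 had 3085 CPM, against 1468 and 1651 CPM in the others. The species of the transgene's Yap sequence is not given in the sources used here, so how much of the transgene is counted as Yap1, beside the endogenous gene, is not known.

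**Figure D1:**
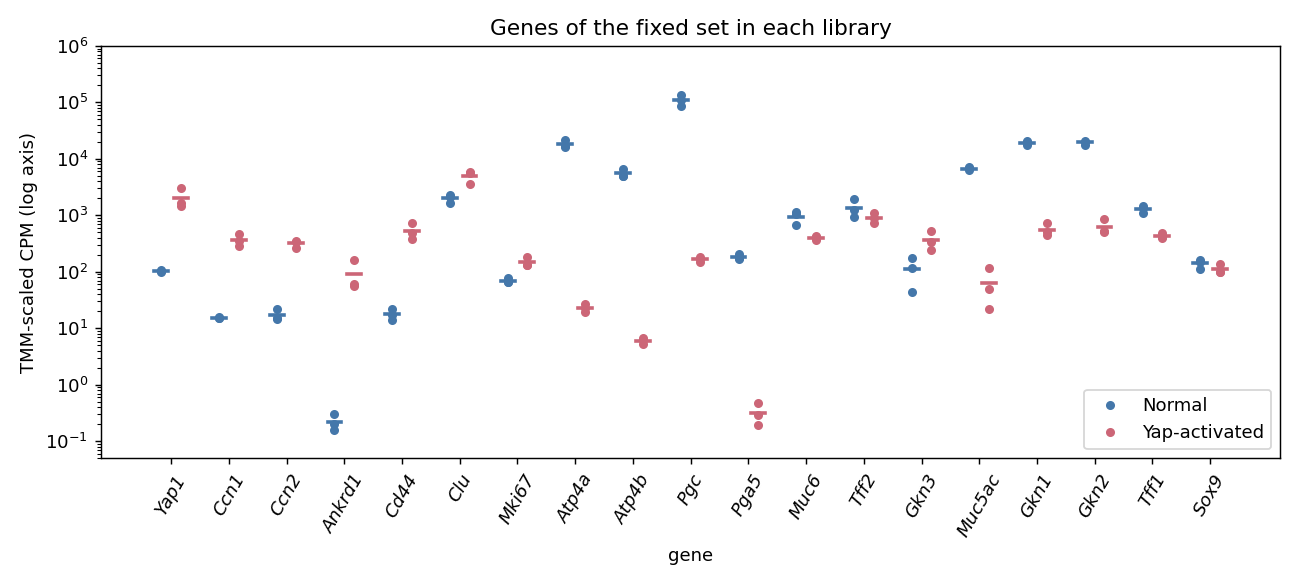
TMM-scaled CPM on a log axis for genes of the fixed set, with 1 point per library (3 Normal, 3 Yap-activated) and a bar at each group's mean. Yap1 averages 104 CPM in Normal and 2068 CPM in Yap-activated libraries, and Atp4a 18324 and 22.8 CPM.

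Among 22 Yap and Taz target genes, 18 rose, 2 fell and 2 did not pass the threshold. Ccn1 rose by a log2 fold change of 4.57 (SE 0.19), Ccn2 by 4.22 (SE 0.21) and F3, the tissue factor gene, by 5.57, while Igfbp3 and Foxf2 were at -1.10 and -0.84. The list was higher by camera (adjusted p = 1.45e-06), but not past the threshold with an estimated correlation (adjusted p = 0.234 with an estimated correlation). Of 22 Hippo pathway components, 14 rose, 15 when adjusted over the list alone, 2 fell and 6 did not pass (adjusted p = 1.32e-04, and adjusted p = 0.234 with an estimated correlation). They include Yap1 itself, Tead4 at 5.31 and Tead2 at 2.48, DNA-binding partners of Yap, and Ajuba at 4.22, while Nf2, an upstream regulator, fell by 0.51 on the log2 scale.

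All 18 parietal cell genes and all 8 tested chief cell genes fell. Log2 fold changes were -9.86 for Atp4b (SE 0.29), -9.65 for Atp4a (SE 0.33) and -9.28 for Kcne2, a potassium channel subunit of acid secretion. Among chief cell genes they were -9.37 for Pgc (SE 0.41), -9.22 for Pga5 and -5.89 for Bhlha15, a transcription factor of secretory cells. The parietal list had adjusted p = 5.16e-11 and the chief list 8.71e-06 by camera, and both had adjusted p = 0.234 with an estimated correlation. Atp4a lies on chromosome 7 from 30712209 to 30725534 and Pgc on chromosome 17 from 47726842 to 47734482 (GRCm38). Pgc alone held 9.45 ± 2.39% of Normal counts and 0.0200 ± 0.00174% of Yap-activated counts (SD, n = 3).

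Surface mucous genes also fell, 9 of 11, with Muc1 higher and Foxq1 at 0.23 not past the threshold (adjusted p = 1.93e-04 by camera, and adjusted p = 0.234 with an estimated correlation). Muc5ac, the secreted mucin of pit cells, fell by 6.73 on the log2 scale (SE 0.69), and Gkn1, Gkn2 and Tff1 had log2 fold changes of -5.11, -4.96 and -1.60. Without Yap-activated replicate 1, the log2 fold change of Muc5ac was -7.53. Of 14 enteroendocrine genes, 11 fell, 1 rose and 2 did not pass, and 12 fell when adjusted over the list alone (adjusted p = 5.66e-05, and adjusted p = 0.362 with an estimated correlation). Ghrl, the ghrelin gene, was at -5.27 and Chga at -5.53, while Gast, the gastrin gene, rose by 2.06. Of 9 tuft cell genes 5 fell, among them Dclk1 at -1.52, 1 rose and 3 did not pass (adjusted p = 0.241 by camera, and adjusted p = 0.757 with an estimated correlation). The riser was Avil at 0.49, a call lost without Normal replicate 1 (0.0807), Normal replicate 3 (0.0742) or Yap-activated replicate 2 (0.0628).

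Genes of mucous neck cells and of spasmolytic polypeptide-expressing metaplasia moved apart. Of 15, 11 rose, 1 fell and 3 did not pass (adjusted p = 0.00163, and adjusted p = 0.423 with an estimated correlation). Cd44, a hyaluronan receptor, rose by 4.92 on the log2 scale (SE 0.32), Cftr, a chloride channel, by 6.36, and Clu by 1.32 (SE 0.24). The Yap-activated mice carried CreERT2 at the Clu gene, and how far that allele changes the Clu count is not known. Muc6, the neck cell mucin, fell by 1.25, and Tff2 and Sox9 had log2 fold changes of -0.58 (adjusted p = 0.119) and -0.34 (adjusted p = 0.138, edgeR quasi-likelihood test). Tff2 passed without Normal replicate 3 (-0.80, adjusted p = 0.0439) and Sox9 without Yap-activated replicate 1 (-0.50, adjusted p = 0.0332), while Sox9 was at 0.14 with library totals alone. Gkn3 rose by 1.73 (adjusted p = 0.0249), a call lost without Normal replicate 3 (0.0763), Yap-activated replicate 1 (0.0561) or Yap-activated replicate 3 (0.0507), and with no filter on low counts (0.0502). Of 13 intestinal metaplasia genes, 7 rose, such as Cdh17 at 5.63, 2 fell and 4 did not pass (adjusted p = 0.256, and adjusted p = 0.706 with an estimated correlation). Of 9 isthmus progenitor and stem cell genes, 4 rose and 4 fell, the latter including Tnfrsf19 at -4.53 (adjusted p = 0.941, and adjusted p = 0.956 with an estimated correlation). That list's median was 0.36 and its mean -0.48, and camera gave it an upward direction.

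Of 18 genes of fetal-like and regenerative epithelium, 17 rose and Spp1, at 0.19, did not pass (adjusted p = 1.01e-09, and adjusted p = 0.17 with an estimated correlation). Clu, the gene that carries CreERT2 in the Yap-activated mice, is among the 17. Msln, the mesothelin gene, rose from 14.1 to 2539 CPM, Krt7 from 29.0 to 2587 CPM, and Anxa8 by 7.18 on the log2 scale. Among 11 genes of the EGF receptor family and its ligands, 9 rose, Egf fell by 2.59 and Erbb2, at 0.07, did not pass (adjusted p = 0.00163, and adjusted p = 0.234 with an estimated correlation). The ligand genes Ereg and Areg rose by 5.62 and 5.35, and Egfr by 2.23. Among 17 Wnt target genes 10 rose, 3 fell and 4 did not pass (adjusted p = 0.112, and adjusted p = 0.623 with an estimated correlation). The list passed by fry, which tests it by itself (adjusted p = 0.0354), and by camera without the members that other lists hold (adjusted p = 0.0281). Ephb2 rose by 2.84, while Lgr5 fell by 1.15 and Axin2 was at 0.45, not past the threshold.

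Cell cycle genes rose, 23 of 25, and 24 when adjusted over the list alone (adjusted p = 2.92e-07, and adjusted p = 0.437 with an estimated correlation). Mki67 rose by 1.09 on the log2 scale (SE 0.15), from 69.5 to 148 CPM, and Cdk1 and Rrm2 by 2.14 and 2.18, while Plk1 fell by 0.73. Of 14 p53 targets and cell cycle inhibitors, 12 rose, 1 fell and 1 did not pass (adjusted p = 6.83e-05, and adjusted p = 0.17 with an estimated correlation). Cdkn2a, which encodes cell cycle inhibitors, rose by 6.39, Gdf15 by 4.61 and Cdkn1a by 1.51. Immediate early genes rose, 14 of 16, with Fosb at 5.50, Dusp1 at 4.82 and Fos at 3.11 (adjusted p = 2.34e-06, and adjusted p = 0.17 with an estimated correlation). The members that did not pass were Hspa1a and Hspa1b, at 0.15 and 0.46.

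Of 19 inflammatory cytokine and chemokine genes, 18 rose and Il18 did not pass (adjusted p = 5.66e-05, and adjusted p = 0.245 with an estimated correlation). Their median log2 fold change was 5.24, with Cxcl5 at 8.84, Tnf at 5.24 and Il1a at 5.35. Cxcl5 had 1622 CPM in Yap-activated replicate 1 and 174 and 349 CPM in the others, and 7.40 as its log2 fold change without that library. Of 16 myeloid cell genes 10 rose and 6 did not pass, with S100a9 at 5.64 and Cd14 at 4.48 (adjusted p = 0.027, and adjusted p = 0.706 with an estimated correlation). S100a9 also stood highest in Yap-activated replicate 1, at 274 CPM against 7.20 and 81.6 CPM, and was at 4.20 log2 without it. With voom S100a9 did not pass (adjusted p = 0.112). The myeloid call was lost without Yap-activated replicate 3 (adjusted p = 0.149), with library totals alone (0.263) and by fry (0.135). Of 17 interferon-stimulated genes, 2 rose, 4 fell and 11 did not pass (adjusted p = 0.403, and adjusted p = 0.82 with an estimated correlation).

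Of 75 nuclear-encoded genes of oxidative phosphorylation 70 fell, and 71 when adjusted over the list alone, with a median log2 fold change of -1.39 (adjusted p = 2.39e-19, and adjusted p = 0.234 with an estimated correlation). Cox7a1, a subunit of cytochrome c oxidase, was at -5.02 on the log2 scale and Atp5b, a subunit of ATP synthase, at -1.78. All 16 genes of fatty acid oxidation fell, such as Hadh at -2.25 and Acaa2 at -2.21 (adjusted p = 5.17e-07, and adjusted p = 0.234 with an estimated correlation). Of 10 tested mitochondrially encoded genes 9 fell, and 10 when adjusted over the list alone, with mt-Nd2 falling by 1.67 (adjusted p = 0.0106, adjusted p = 0.0514 by fry, and adjusted p = 0.655 with an estimated correlation). All 18 parietal cell genes fell too, at a median log2 fold change of -6.16. The falls in these 3 lists therefore cannot be told apart from a loss of parietal cells. The mitochondrial share of counts was 19.6 ± 6.93% in Normal and 10.2 ± 3.25% in Yap-activated libraries (SD, n = 3; 2-sided exact permutation p = 0.1, the smallest possible). Replicate 1 stood highest in both groups, with 27.6% against 16.1% and 15.1% in Normal and 13.8% against 7.49% and 9.30% in Yap-activated tissue. Of 14 glycolysis genes 7 rose, 1 fell and 6 did not pass, and 6 rose when adjusted over the list alone (adjusted p = 0.0872, and adjusted p = 0.757 with an estimated correlation). Hk2, a hexokinase, rose by 2.72 and Ldha by 1.06, and Pkm was at 0.01. The glycolysis list passed the threshold without Yap-activated replicate 1 (adjusted p = 0.00271).

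Among 78 tested genes of cytosolic ribosomal proteins 48 rose and 1 fell, and 50 rose when adjusted over the list alone (adjusted p = 1.45e-06, adjusted p = 0.0622 by fry, and adjusted p = 0.655 with an estimated correlation). Rps3 rose by 0.92 on the log2 scale and Rps10 by 1.20. Of 37 proteasome genes 18 rose, such as Psma5 at 1.10, 1 fell and 18 did not pass (adjusted p = 0.00332, and adjusted p = 0.655 with an estimated correlation). Of 16 genes of ribosome biogenesis and Myc targets 5 rose, 4 when adjusted over the list alone, among them Npm1 at 1.32, and 2 fell (adjusted p = 0.434, and adjusted p = 0.863 with an estimated correlation). Of 15 genes of the unfolded protein response 3 rose, among them Trib3 at 3.16, 5 fell, among them Xbp1 at -1.39, and 7 did not pass (adjusted p = 0.369, and adjusted p = 0.81 with an estimated correlation).

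Epithelial structural genes changed in both directions. Of 25 tested keratin genes, from 53 in the list, 12 rose, 1 fell and 12 did not pass, with Krt7 at 6.48 and Krt19 at 1.04 (adjusted p = 1.41e-04, and adjusted p = 0.437 with an estimated correlation). Of 13 tested claudin genes, from 23 in the list, 7 rose, such as the tight junction genes Cldn4 at 8.44 and Cldn7 at 7.03, Cldn8 fell by 6.51 and 5 did not pass, Cldn18 at 0.21 among them (adjusted p = 0.00511, and adjusted p = 0.234 with an estimated correlation). With library totals alone the claudin list did not pass (adjusted p = 0.0707), and Cldn18 did (adjusted p = 0.0154). Of 11 squamous forestomach genes 1 rose, Ivl at 7.35, and 10 did not pass (adjusted p = 0.0325, and adjusted p = 0.655 with an estimated correlation). Without Normal replicate 1, the log2 fold change of Ivl was 8.52. Krt13 had 16.7 CPM in Normal replicate 2 and 0.582 and 0.0316 CPM in the other Normal libraries, and its log2 fold change went from 2.17 to 6.37 without that library, where it passed (adjusted p = 0.00165), as did Krt4 (5.96, adjusted p = 0.00488) and Krt15 (3.36, adjusted p = 7.45e-04). Krt4, Krt15 and Krt13 also passed with voom (adjusted p = 0.0141, 0.0121 and 0.0192), and Krt4 without Yap-activated replicate 1 (adjusted p = 0.0478). The squamous call was lost without Normal replicate 1 (adjusted p = 0.0808), Normal replicate 3 (0.0737) or Yap-activated replicate 1 (0.0544), with library totals alone (0.27), by fry (0.0622) and without the members that other lists hold (0.226).

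Genes fixed as markers of other cell types gave mixed results. Of 9 endothelial genes 8 fell, among them Kdr at -2.45 and Plvap at -2.37 (adjusted p = 0.00148, and adjusted p = 0.437 with an estimated correlation). Of 12 fibroblast genes 2 rose, 4 fell, such as the collagen gene Col3a1 at -1.68, and 6 did not pass (adjusted p = 0.331, and adjusted p = 0.798 with an estimated correlation). Of 9 smooth muscle genes 4 fell, such as Lmod1 at -1.54, and 5 did not pass (adjusted p = 0.32, and adjusted p = 0.798 with an estimated correlation). Of 7 tested lymphoid genes, from 15 in the list, Gzma rose by 3.92, and 6 did not pass; adjusted over the list alone, 0 passed edgeR's test (adjusted p = 0.339, and adjusted p = 0.757 with an estimated correlation). Gzma had 4.95 CPM in Yap-activated replicate 1 and 0.453 and 0.688 CPM in the others, and was at 2.14 log2 without that library. Its call was lost without Normal replicate 2 (adjusted p = 0.0601) or Normal replicate 3 (0.0666). Of 4 tested erythroid genes, from 7 in the list, 0 passed edgeR's test, 0 had an unadjusted p under 0.05, and Alas2 passed with DESeq2 (adjusted p = 0.0452). Hbb-bs was at 1.37, and the list did not pass (adjusted p = 0.434, and adjusted p = 0.798 with an estimated correlation). Of 11 genes fixed as markers of pancreatic acinar cells, 7 had too few reads to be tested, Clps and Pnliprp1 were lower, at -9.27 and -8.43 on the log2 scale, and Cela1 and Ctrl did not pass (adjusted p = 0.0938, and adjusted p = 0.437 with an estimated correlation). Normal libraries averaged 9477 CPM for Clps, the colipase gene, and 0.443 CPM for Ctrl, a chymotrypsin-like protease gene. The list passed without any one of Normal replicate 1 (0.0205), Normal replicate 3 (0.0161) or Yap-activated replicates 1 (0.0351), 2 (0.0357) and 3 (0.0459), with library totals alone (0.036), with no filter on low counts (0.0148), with at least 1 CPM required in 3 libraries (0.0356) and by fry (1.32e-04). Of 9 neuron and glia genes 3 rose, such as S100b at 2.56, 4 fell and 2 did not pass (adjusted p = 0.852, and adjusted p = 0.867 with an estimated correlation).

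Over the 37 lists, camera with the preset correlation called 15 higher and 8 lower. With an estimated correlation it called 0 higher and 0 lower (6 and 1 at an unadjusted p under 0.05), and fry, which tests each list by itself, called 13 and 8. The estimated correlation was -0.0303 for immediate early genes and 0.00558 for p53 targets and cell cycle inhibitors, below the preset 0.01. These lists still had adjusted p = 0.17 by camera with it, so a high correlation is not why they did not pass. Every split of the 6 libraries that mixes the groups gave 16 to 23 list calls with the preset correlation, against 23 in the real split. Each such split has more libraries of one group on one side, so part of the difference between the groups stays in it. Its calls are therefore not a rate of false calls. The splits cannot decide how far the preset correlation inflates the calls. In the lists where no other number is given, the counts adjusted over the list alone equal those over all genes tested.

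**Figure D2:**
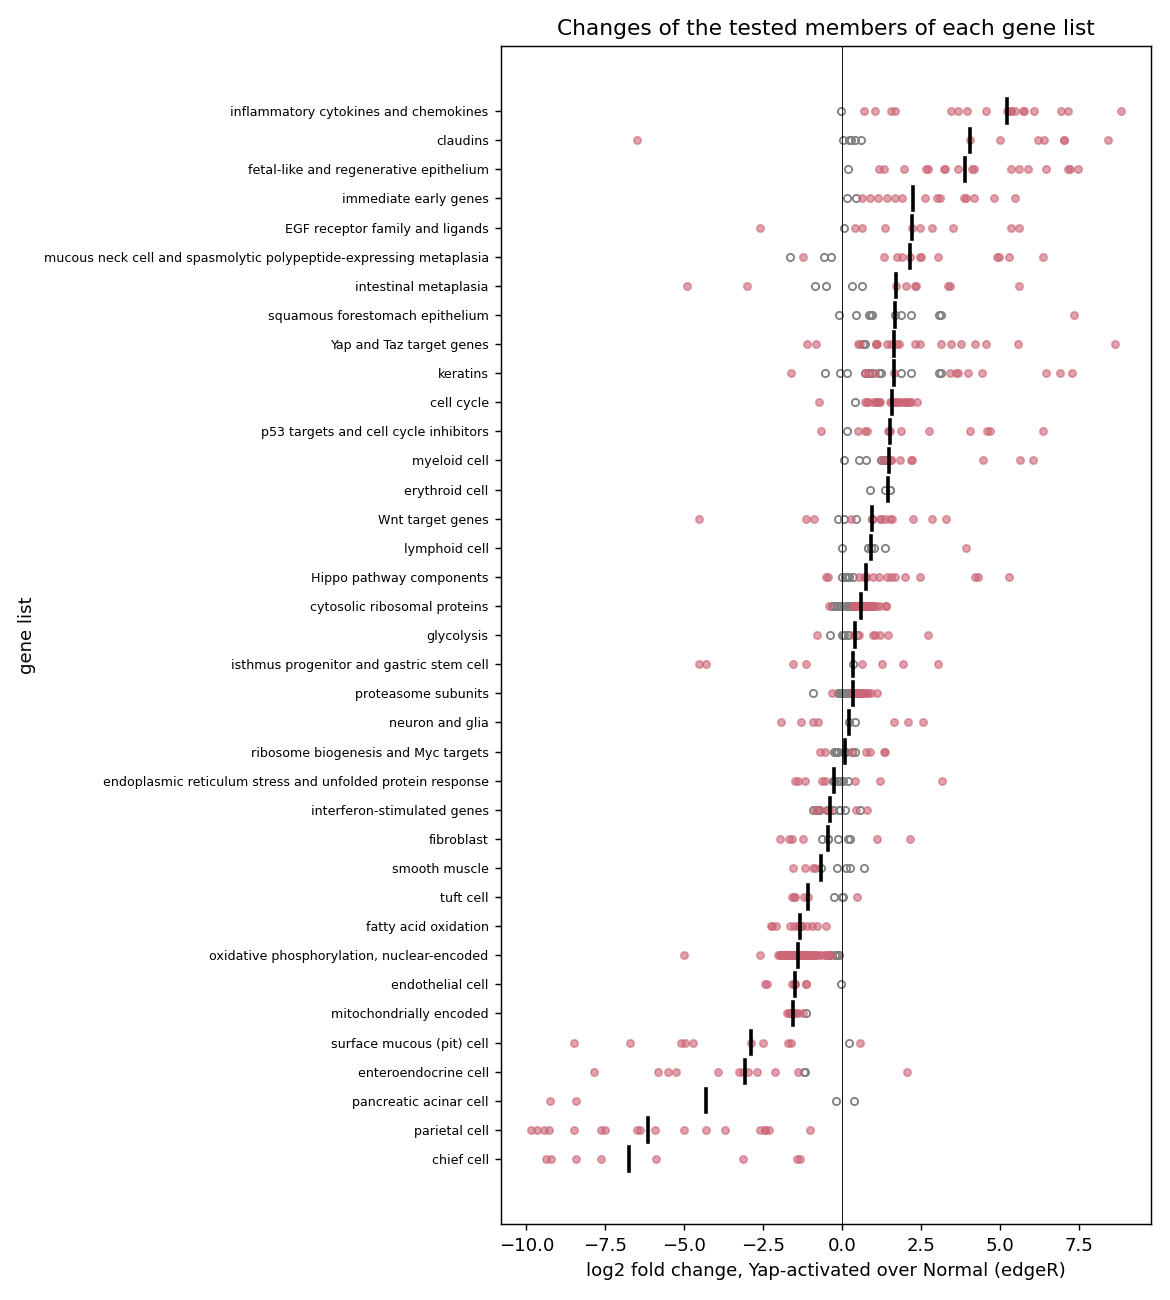
Log2 fold change of Yap-activated over Normal for each tested member of the 37 gene lists, with filled points for members past the threshold, open points for the others and a bar at each list's median. Medians run from -6.76 for chief cell genes to 5.24 for cytokines and chemokines.

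The largest rise among the genes eligible for naming was that of Wnt7a, a secreted Wnt ligand, with a log2 fold change of 9.45 (SE 0.61, adjusted p = 2.00e-05, edgeR quasi-likelihood test) from 4 reads in Normal to 3453 in Yap-activated libraries. Pbp2 had 2 reads in Normal and 1399 in Yap-activated libraries, a ratio of 604 with a 95% counting interval from 167 to 4989. Both Normal reads were in replicate 2, and the fitted log2 fold change, which is no bound at such counts, was 9.15, 11.87 without that library and 8.43 without Yap-activated replicate 1. Asz1, on chromosome 6 from 18050964 to 18109061, rose by 9.14 (SE 0.17) and Prss22, a serine protease gene, by 8.74. Ankrd1 rose by 8.64, Serpinb9b by 8.60, Mab21l3 by 8.54 and Cyp21a1, a steroid 21-hydroxylase gene, by 8.53. Dynap rose by 8.57, with 49.4 CPM in Yap-activated replicate 1 and 4.91 and 2.49 CPM in the others, and by 6.25 without that library. Without Yap-activated replicate 1, Ankrd1 was at 7.98.

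The largest falls beside Atp4a, Atp4b and Pgc were those of Rnase1 and Cst8, with log2 fold changes of -9.58 and -9.54, and with 6 and 4 reads in Yap-activated libraries. Pnliprp2, a lipase gene, was at -9.50, Trim50 at -9.47, Kcnj16, a potassium channel gene, at -9.45, Pla2g1b, a secreted phospholipase, at -9.40 and Tmprss9 at -9.36. Without Yap-activated replicate 3, Rnase1 was at -10.26. Atp4b was at 5539 ± 1043 against 5.96 ± 0.726 CPM (SD, n = 3).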

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

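Most calls kept their direction and side of the threshold under the alternatives. Counts of genes moved by over 1.5 times with library totals alone (7522 higher, 2299 lower, and 4120 and 1426 by over 2-fold) and in the test against a 2-fold change (1594 and 1454). Of 9821 calls with library totals alone, 6645 were shared with TMM and 1 was reversed. With an estimated correlation, 0 lists were higher and 0 lower. Sox9, Hspa5 and Stat2 reversed with library totals alone (0.14, 0.23 and 0.12). So did the direction that camera gave the neuron and glia list, whose mean stayed above 0 (0.67). Pkm, near 0, reversed with voom (-0.0225), with the replicate block (-0.0039), without Normal replicate 2 (-0.03) and without Yap-activated replicate 3 (-0.12). The tested direction of the isthmus and stem cell list, upward by camera with a mean below 0, turned with library totals alone (mean 0.0018), with fry (-0.50) and without Normal replicate 1 (-0.54), Normal replicate 3 (-0.51) or Yap-activated replicate 2 (-0.56; -0.56 to -0.39 over all libraries left out). Except where stated, the cause was not tested. With library totals alone Trpm5, Irf7, Polr1a, Acta2, Myl9 and Myh11 lost the call, and Pkm, Psmd2, Cldn18, Cd79a, Il7r, Jchain, Alas2, Krt4 and Krt15 gained one. Il7r, Jchain and Alas2 also passed without Yap-activated replicate 2. The calls of Erbb3, Ephb3, Irf7, Irf9, Stat2, Oasl1, Ncl, Acta2, Myl9 and Myh11 were each lost without at least 1 of the libraries (adjusted p from 0.0505 to 0.138, edgeR quasi-likelihood test). Leaving out 1 library gave 3530 to 4304 genes higher and 3674 to 4273 lower, and 3.92 to 4.51 for Yap1. Same-numbered samples had deviations from their group's mean correlated at 0.0400, 0.0027 and 0.0690, and differently numbered samples at -0.111 to 0.0664. With so few libraries in each group this cannot exclude that samples of the same number share a batch. Replicate 1 had the highest mitochondrial share in both groups. With the replicate block 4239 genes were higher and 4322 lower, Yap1 was at 4.24, and 14 lists were higher and 8 lower. With it the squamous list (adjusted p = 0.0934 by camera), Gkn3 (0.0625) and Trpm5 (0.0554) did not pass, and Krt4 (0.0328) and Krt15 (0.0283) did. DESeq2 called 4562 and 4393, with 5419 adjusted p-values not given. Thinned to the smallest library, the counts were 4239 and 4155, so depth sets few calls.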

Other observations

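The gene groups in the first 2 paragraphs were chosen after the genes had been seen, as were the comparison of cytokines with myeloid markers, the comparison of immediate early genes with all genes and the check for look-alike symbols. The list p-values of groups chosen in this way describe the chosen genes and carry no weight as evidence that a group changed. All 19 tested genes of branched-chain amino acid and ketone oxidation fell in Yap-activated tissue, with Aldh6a1 at -5.26 and Oxct1, the ketone body transferase, at -4.31 on the log2 scale (adjusted p = 2.75e-12 by camera, and adjusted p = 0.242 with an estimated correlation). All 16 tricarboxylic acid cycle genes fell, Ogdh at -2.69 and Idh2 at -2.53 (adjusted p = 3.51e-08, and adjusted p = 0.242 with an estimated correlation). Like those of oxidative phosphorylation, these falls cannot be told apart from a loss of parietal cells, whose 18 genes all fell. Of 18 genes induced by hypoxia 13 rose and 5 did not pass, with Hilpda at 4.89 and Bhlhe40 at 2.98, while Vegfa at 0.69 and Car9 at -0.35 were not past the threshold (adjusted p = 0.00402, and adjusted p = 0.649 with an estimated correlation).

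Of 22 laminin and epithelial integrin genes 14 rose, 5 fell and 3 did not pass (adjusted p = 0.00242, and adjusted p = 0.363 with an estimated correlation). Itga2 rose by 7.16 and Lama3 by 4.98, while Lama2 and Lama4 were at -2.82 and -2.34. Of 12 genes of plasminogen activation 9 rose, 1 fell and 2 did not pass, with Plat at 6.85 (adjusted p = 0.00242, and adjusted p = 0.242 with an estimated correlation). Of 22 transcription factors of stomach and foregut 6 rose, 11 fell and 5 did not pass (adjusted p = 0.198, and adjusted p = 0.708 with an estimated correlation). Onecut2 rose by 8.13, from 1.83 to 520 CPM, and Pdx1 by 3.30, while Gata4 was at -2.07, Esrrg at -7.51 and Hnf4a, not past the threshold, at -0.06. Among 244 gene families taken from symbols, camera called 9 higher, such as Serpinb (9 of 10 rose) and Mmp (12 of 18 rose), and 8 lower, such as Ces (9 of 11 fell). None of these families passed with an estimated correlation (adjusted p = 0.906 for Serpinb, Mmp and Ces).

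The design allows 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split was the 1 split with 8682 genes past the threshold, and the highest of the others had 0 by edgeR's quasi-likelihood test, with at most 236 genes at an unadjusted p under 0.05. For gene lists, 3 of the 10 splits reached the 23 calls of the real split, and the splits that mix the groups had 16 to 23. A mixed split keeps part of the group difference and puts the rest into the spread within its sides. Neither its gene calls nor its list calls therefore show what libraries without a difference would give.

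The cytokine and chemokine genes rose more than markers of myeloid cells. More leukocytes in the same proportions as in normal tissue, with unchanged expression in each cell, would raise both alike. The median cytokine change exceeded the median myeloid change by 3.04 ± 0.94 log2 (SD over the 3 Yap-activated libraries). That argues against such a proportional rise as the whole cause, though it restates the changes of the lists given above and is no separate test. A rise of only some kinds of leukocytes already in normal tissue, neutrophils among them, is not excluded. Neutrophils entering the tissue remain a candidate explanation: of 10 tested neutrophil markers, from a list of 14 written before their values were seen, 9 rose. Their median log2 fold change was 4.45, with Mmp9 at 30.9 CPM and Csf3r at 27.4 CPM in Yap-activated libraries. Ly6g, Ngp, Camp and Stfa2l1 had too few reads to be tested. Median log2 changes were 5.32, 2.05 and 4.56 in Yap-activated replicates 1, 2 and 3. The list had adjusted p = 0.0173 by camera, and adjusted p = 0.649 with an estimated correlation. Of the 10 tested markers, 4 were above 1 CPM in Normal, none is in another fixed list, and Ltf, the most abundant at 167 CPM, did not pass (adjusted p = 0.057, edgeR quasi-likelihood test). Cytokine expression by the epithelium itself and higher cytokine expression in each leukocyte were not tested and stay open. Per the labels, the EDTA isolation had no sort that would remove leukocytes.

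The rise of immediate early genes could come from stress during cell isolation. Such stress, where it induces heat shock genes too, would raise both. But 10 heat shock genes fixed before their values were seen had a median log2 fold change of 0.10, with 2 higher and 8 not past the threshold. The SE of that median was 0.17 in a bootstrap over the 10 genes, which does not cover the spread between libraries. Scaling between libraries moves all genes of a library alike, but the median change of the immediate early list exceeded that of all genes tested by 2.19 ± 0.04 log2 (SD over the 3 Yap-activated libraries). That argues against scaling as the whole cause, though it restates the list's rise given above and is no separate test. Isolation stress without heat shock induction and induction in the tissue with Yap activation both stay open.

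Genes raised over 16-fold often lay beside another raised gene, for example Duox2 beside Duoxa2 (4.39 and 5.94 log2), a pattern looked for after Asz1 and Cftr had been seen, which lie farther apart than the 50 kb searched. Of 322 such genes, 18.3% had a neighbour within 50 kb with another symbol stem that was raised over 4-fold, against 9.01% in 1000 random sets matched on expression (95% of sets between 6.21% and 12.1%). Tandem copies that share a symbol stem are therefore unlikely to be the whole cause. Without neighbours of look-alike symbols the share was 15.8%, against an upper limit of 12.1% for random sets. Families were judged by symbols alone, so tandem copies with unlike symbols are not excluded. Read-through from an upstream gene on the same strand may contribute, and cannot be told apart from shared regulation. Here only same-strand neighbours within 50 kb were counted, with those of the same symbol stem kept in. Of these, 34 of 111 upstream (30.6%) and 38 of 108 downstream (35.2%) were raised over 4-fold. The difference was -4.55 percentage points (1-sided Fisher's exact test for an upstream excess, p = 0.805). Shared regulation was not tested.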
